A study of Mus musculus with 2 samples.

How the data were processed

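RNA-seq libraries were prepared with a SMARTER mRNA-seq kit from 1.5 µg of total RNA of mouse intestinal organoids on day 6 of culture, per the labels' protocols. The samples formed 2 groups by their genotype label, with 1 library each. The files held comparisons made by the authors, in a table of genes and a table of transcripts, and no level or count per library. For each comparison the authors deposited a log2 fold change, which per the file headers sets the F4KO library against the WT library and whose antilog is nearly always a ratio of whole numbers, as from rounded levels. They also deposited a p-value from a test that the file headers name after the Poisson distribution, and a false discovery rate (FDR) computed from it. That FDR equals the p-value times the number of tested genes over its rank, without a limit at 1, so that 767 genes had a deposited value above 1, up to 1.02. The builds GRCm38 and mm10 are named in the submitters' processing notes. The aligner, the quantifier, their versions and the annotation are not given in the sources used here. The design fixed before the data were examined assumed normalized levels for each library. These were not found in the tables used here, so the deposited fold changes and FDR took their place. No level, pseudocount or count test of the kind planned was used.

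The tables also hold a second comparison, whose headers name Epi libraries of WT and F4KO. The labels used here describe no such libraries, so the report leaves this comparison out and the closing section gives its values under that name.

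Read numbers were recovered from the deposited p-values. The deposited p-value of a gene is a function of its 2 whole read numbers and the ratio of the library totals (the Audic-Claverie test, two-sided), which was found by matching the p-values of genes with 0 reads in 1 library, to a mean relative error of 1.1e-06. All pairs of fewer than 1000 reads were set against each p-value, with a relative tolerance of 7e-06, and against the deposited fold change, which for 99.1% of genes was a ratio of whole numbers within a relative 1e-11. A pair was printed only where it alone fitted and its total was at most 400 reads or the p-value was under 1e-06. This gave 5951 genes, and when the p-values were shifted by 0.03%, which leaves only false matches, 89 genes still matched, a false rate of 1.50%. Above 400 reads it was 1 of 138 (0.725%). For genes with at least 20 reads in each library the recovered ratio differed from the deposited log2 fold change by up to 0.37, and how the levels were made is not given in the sources used here. Among 1121 genes with 200 to 400 recovered reads, log2 ratios had an SD across genes of 0.49, against 0.18 from counting alone. The first SD is widened by a few extreme genes, among them Ddx3y, Fam177a2 and Uty. These had 1 and 230, 1 and 354, and 30 and 208 reads in WT and F4KO. An SD without them was not computed.

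Where several pairs fitted a gene, the pair with the fewest reads set its total for filters. A gene that no pair fitted was counted as above each read limit, unless its level was coarse and a looser match of its ratio gave a pair. A gene with few reads, such as Flt1, can thus count as measured. These rules for totals were settled after list results had been seen. They left the immune and the endothelial lists with 2 measured members each and no percentile, and the alternative of taking the median of the fitting pairs is given in the closing section. The PPAR list lies so close to the limit that earlier handling of read totals put it on either side. Its call is borderline.

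With 1 library per genotype no test of genotype was made. Genes and transcripts were counted by a rule of size, a deposited log2 fold change of at least 1 in either direction with a deposited FDR of 0.001 or less, chosen after the files were opened. Gene lists were fixed before the data were examined. A list member counted as measured with at least 20 reads over both libraries. The median of a list's deposited log2 fold changes was placed among 10000 random lists of the same size matched on level in 20 bins (seed 1), and a list stood apart when its median lay in the outer 2.5% on either side. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the deposited p-values of the measured members, with the same limit of 0.001. The lists covered intestinal stem, Paneth, goblet, enteroendocrine, tuft and enterocyte markers, cell cycle, fetal-like epithelium, secreted antimicrobial proteins, fatty acid binding proteins, PPAR targets, cholesterol and fatty acid synthesis, the unfolded protein response, NF-kB targets, interferon-stimulated genes, class II histocompatibility genes, tight junctions, hypoxia, NRF2, 3 intestinal regions, mitochondrial DNA, sex-linked genes and markers of immune, fibroblast, adipocyte, endothelial and pancreatic or stomach cells. A list of 6 X-linked genes that escape inactivation and the group of all X-linked genes were added later, after the Y-linked values had been seen. In the closing section, the test of immune cells replaced a first form, already run, that had left out Itgam and Cd68, and the test of the defensins replaced one that took the Paneth list without them. For 6 defensin genes without a printed read pair, reads were estimated from the deposited p-value and fold change by a normal approximation.

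The named genes follow a rule set before the data were examined, carried over to the deposited values. They are Fabp4, the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the size rule, leaving out predicted and unnamed genes, and members of the lists with at least 100 reads over both libraries. For a list that stood apart these are up to 4 members with the largest absolute fold change, and for other lists up to 2 with the highest level. Fatty acid binding proteins and sex-linked genes are named throughout. A gene that the rule names is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

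Read ratios have exact 95% Clopper-Pearson intervals after division by the ratio of read totals. A ratio against 0 reads is given by the limit of its interval that lies nearer to 1, and other read ratios by both limits. Reads without molecular identifiers are not independent molecules, so both cover counting error only. Gene coordinates are from GENCODE vM21 on GRCm38, counted from 1. Of the 17219 genes, 17172 (99.7%) matched NCBI RefSeq of GRCm38.p6 by gene ID, which was used for chromosomes.

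The procedure was tested on simulated data for the organoid comparison, with reads drawn for 15336 genes, of which 200 were changed. Of 5452 read pairs that met the printing rule 99.7% were those simulated. Of 15136 unchanged genes 0 were past the size rule, and of 50 genes at each fold size 0% passed at 1.5-fold, 44% at 2-fold, 100% at 3-fold and 100% at 4-fold. Of 100 random lists of 20 genes 5 stood apart, and of 100 lists shifted by 0.3 on the log2 scale 100 did. The simulation holds counting error only and genes that vary independently, so it says nothing of variation between cultures or of lists whose genes vary together. Alternatives tried were other FDR and fold limits, other read limits, rescaling of the fold changes, and leaving out X and Y or a region of chromosome 2. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.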

Results

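The series asked how the loss of FABP4, a fatty acid binding protein best known from adipocytes and macrophages, alters gene expression in intestinal epithelium. Crypts of mouse intestine were grown in Matrigel as organoids, cultures in which stem cells and the differentiated epithelial cell types grow together, and RNA was taken on day 6. One genotype carried floxed Fabp4 alleles together with a villin-Cre transgene, which acts in intestinal epithelium, and is called F4KO here. The other carried the floxed alleles alone and is called WT. The titles and the design text call the first genotype a knockout, whereas its genotype label says knockdown. Each genotype had 1 library, so there were no replicates and no difference given here has a replicate check. The deposited FDR compares the 2 libraries, not the genotypes. The authors' deposited table held 17219 genes, 15845 of them with a fold change, and no level per library. Total depth is therefore unknown, but read numbers could be recovered from the deposited p-values for 5951 genes, and the read total of F4KO was 0.992 times that of WT. Fold changes were read as F4KO over WT from the order of the names in the file headers, which nothing else in the sources states. Intervals of read ratios are exact 95% Clopper-Pearson intervals and cover counting error only.

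Fabp4 was close to undetected in both organoid libraries. The gene (gene ID 11770, minus strand of chromosome 3 from 10204088 to 10208576, GRCm38) had 1 read in the WT library and 0 in the F4KO library, so a difference was not detectable at this depth. The authors' deposited table lists it with a log2 fold change of -3.58 and an FDR of 0.719. Of its 2 listed transcripts, 1 had a fold change in the authors' deposited table of transcripts, with a log2 value of -3.58 and an FDR of 0.616. Fabp4 therefore checks neither the genotype labels nor the direction of the fold changes, and the deleted part of the gene is not given in the sources used here.

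Most genes differed little between the organoid libraries. Y-linked genes were higher in the F4KO library, as were the list medians of secretory cells (Paneth, goblet and enteroendocrine). List medians of stem cells, the cell cycle, fetal-like epithelium and the interferon response were lower, although most members of these lists did not pass an FDR of 0.001, with 8 of 23, 11 of 25, 7 of 15 and 2 of 21 lower at that limit in the authors' deposited table. Among 12187 genes with at least 20 reads over both libraries, 92.7% differed by less than 1.5-fold, and the median deposited log2 fold change was -0.01 with quartiles of -0.19 and 0.12. By the size rule, a deposited fold change of at least 2 with a deposited FDR of 0.001 or less, 17 genes were higher and 38 were lower in the F4KO library. At the same FDR and any fold, 489 genes were higher and 745 were lower. Of the 55 genes past the size rule, 5 lay on Y, all higher, and 3 on X (Fmr1nb, Nxf7 and Tceal8), all lower, which left 12 higher and 35 lower genes elsewhere. Nxf7 and Tceal8 were named after their values were seen.

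**Figure D1:**
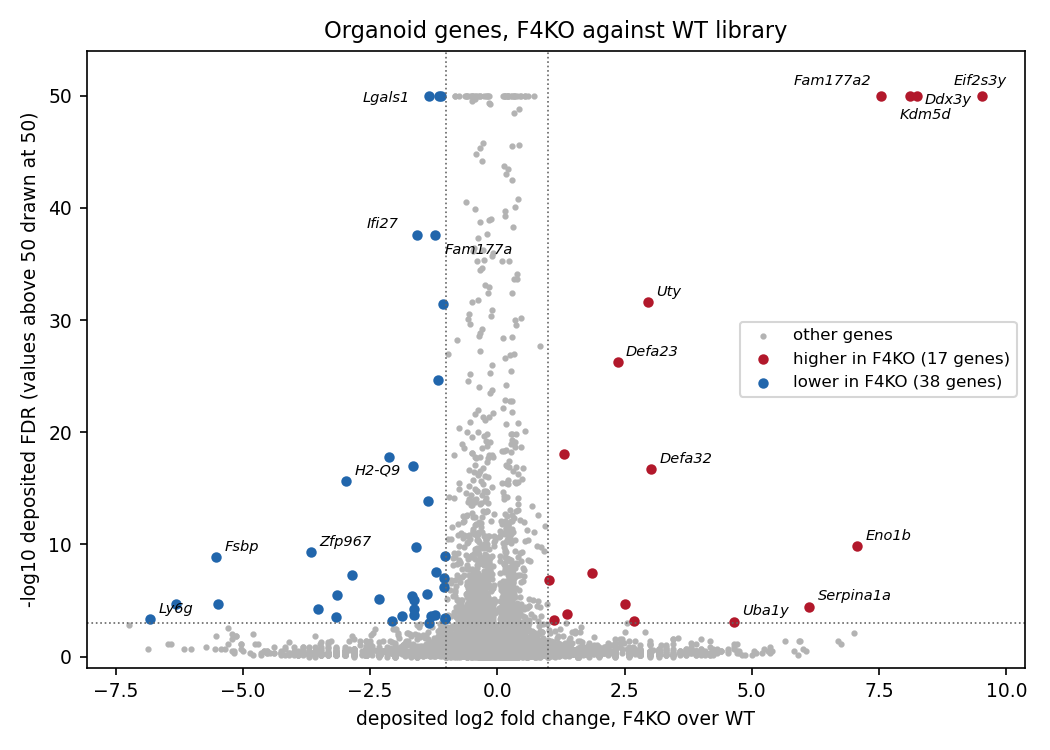
Each point is a gene of the organoid comparison, with the deposited log2 fold change of F4KO over WT on the x axis and -log10 of the deposited FDR on the y axis, where values above 50 are drawn at 50. Dotted lines mark 2-fold and an FDR of 0.001, and the 17 genes higher and 38 genes lower in the F4KO library lie outside them, with Eif2s3y farthest to the right at 9.53 and Ly6g farthest left among the named genes at -6.82.

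The 3 highest fold changes of the organoid comparison were those of the Y-linked genes Eif2s3y, Ddx3y and Kdm5d. Eif2s3y, a translation initiation factor subunit (chromosome Y, 1010543 to 1028847), had 879 reads in the F4KO library and 1 in WT, a ratio whose interval ran from 159 to 35037. Ddx3y, an RNA helicase (chromosome Y, 1260771 to 1286629), had 230 reads in F4KO and 1 in WT, with an interval from 41.2 to 9197. Kdm5d, a histone demethylase (chromosome Y, 897788 to 956786), had 249 reads in F4KO and 0 in WT, with a lower limit of the ratio of 67.5. Uba1y, a ubiquitin-activating enzyme, had 14 and 0 reads, with a lower limit of 3.34. Uty, whose X-linked relative is Kdm6a, had 208 reads in F4KO and 30 in WT, with an interval of the ratio from 4.75 to 10.6. All 4 measured members of the sex-linked list fixed before the data were examined were past the size rule, with 4 at an FDR of 0.001 or less in the authors' deposited table and 4 adjusted over the list alone. The X-linked genes Xist and Tsix of that list were not analysed here.

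The median of X-linked genes was slightly lower in the F4KO library, although most of these genes did not pass the FDR. Across 365 X-linked genes, grouped by chromosome only after the Y-linked values had been seen, the median deposited log2 fold change was -0.14, at percentile 0 of level-matched random lists, with 113 above 0. In the authors' deposited table, at an FDR of 0.001 or less, 50 were lower and 5 higher, 53 and 5 adjusted over the list alone, and 310 did not pass. By comparison, the medians of the autosomes ran from -0.09 to 0.03. A list of 6 X-linked genes that escape X inactivation was written after the Y-linked values had been seen. All 6 were lower, with a median of -0.47, 5 of them at an FDR of 0.001 or less in the authors' deposited table and 6 adjusted over the list alone. Kdm6a, a histone demethylase (chromosome X, 18162575 to 18279936), had 420 reads in WT and 227 in F4KO, a ratio with an interval from 0.462 to 0.642. For Eif2s3x, the X-linked partner of Eif2s3y, the authors' deposited table gave a log2 fold change of -0.82 and an FDR of 2.52e-176, and for Ddx3x -0.50 and 3.06e-50. Sex of the animals is not given in the labels, and the libraries differ in these genes as well as in genotype throughout the comparisons that follow.

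**Figure D2:**
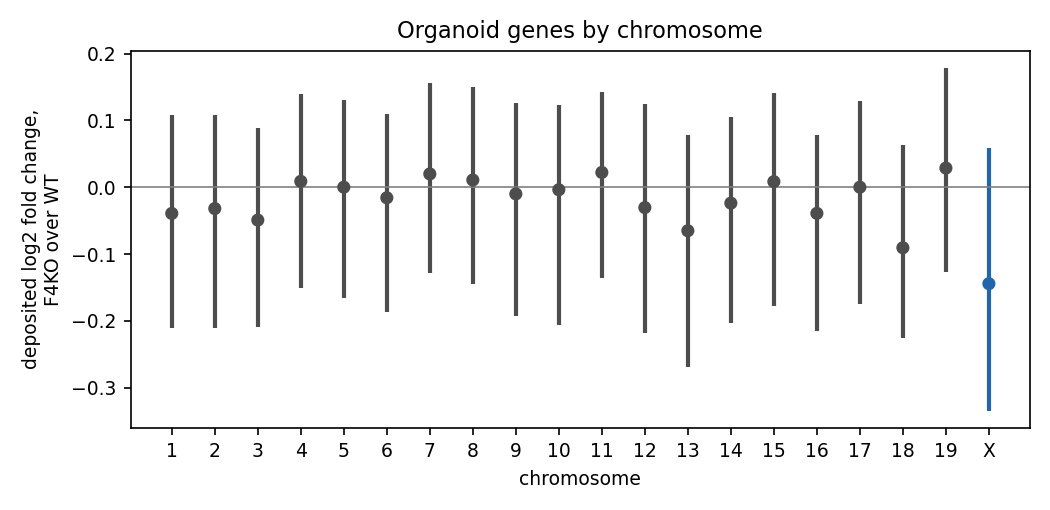
Median deposited log2 fold change of F4KO over WT for the genes with at least 20 reads on each autosome and on X, with bars from the lower to the upper quartile; Y is not drawn. The X chromosome, in blue, has a median of -0.14, below all autosomes, whose medians lie between -0.09 and 0.03.

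Several of the other largest differences were in genes with near-identical copies or overlapping neighbours, between which reads cannot be placed with certainty, so their values are uncertain. Fam177a2 had 354 reads in F4KO and 1 in WT, a ratio with an interval from 63.6 to 14134, while its copy Fam177a was lower, at -1.23 on the log2 scale in the authors' deposited table. Eno1b, a copy of the glycolytic enzyme gene Eno1, had 38 reads in F4KO and 0 in WT (lower limit of the ratio 9.89), and Serpina1a, one of a cluster of alpha-1 antitrypsin genes, had 19 and 0 (lower limit 4.70). The histone gene H2ac13 had 39 reads in F4KO and 7 in WT. On the lower side, Fsbp, which overlaps a neighbouring gene, had 35 reads in WT and 0 in F4KO (upper limit of the F4KO over WT ratio 0.112). H2-Q9, a class I histocompatibility gene with close copies, had 99 reads in WT and 12 in F4KO, and the prolactin family gene Prl2c3 had 33 and 3, with intervals of the F4KO over WT ratio from 0.0611 to 0.223 and from 0.0180 to 0.292. The zinc-finger genes Zfp967 (chromosome 2, 176521056 to 176532479) and Zfp965 (chromosome 2, 175469985 to 175482171) were lower, at -3.66 and -2.84 on the log2 scale in the authors' deposited table. From Gm14444 to Zfp970 on chromosome 2 (175010241 to 177478129), a region of related zinc-finger genes chosen after its values were seen, 6 of 21 genes with a fold change were past the size rule and 5 of these were lower.

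Further genes among the largest differences belonged to varied functions, and whether they have close copies was not examined. Krt15, a keratin, had 25 reads in F4KO and 4 in WT, with an interval of the ratio from 2.18 to 24.9. Ly6g, known as a neutrophil surface marker, had 15 reads in WT and 0 in F4KO (upper limit of the F4KO over WT ratio 0.281). Fmr1nb (25 and 2 reads), Gcnt7, a glycosyltransferase (22 and 2 reads), Mb, which encodes myoglobin (34 and 8 reads), and Nrgn, which encodes neurogranin (74 and 23 reads), were lower in F4KO, each pair given as WT and F4KO. The intervals of their F4KO over WT ratios were 0.00926 to 0.323, 0.0104 to 0.373, 0.0949 to 0.522 and 0.187 to 0.506. Ttc25, a gene of ciliated cells, was lower at -1.87 on the log2 scale with an FDR of 2.61e-04 in the authors' deposited table. Named after their values were seen, the galectin gene Lgals1 (-1.34), the myosin light chain gene Myl9 (-1.15), the secreted phospholipase gene Pla2g5 (-1.16) and the imprinted growth genes Igf2 (-1.34) and Dlk1 (-1.23) were also lower in F4KO, as log2 fold changes of the authors' deposited table. Igf2 had 62 reads in WT and 25 in F4KO, and Pla2g5 had 554 and 247.

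Of the 30 gene lists fixed before the data were examined, 27 had enough measured members for a percentile, and the medians of 11 of these lay in the outer 2.5% on either side of 10000 level-matched random lists, 6 higher and 5 lower. For lists of genes that vary independently, 1.35 would be expected. Genes of a list can vary together between any 2 cultures and some lists share genes such as Fabp1, so 1.35 does not tell what 2 cultures of 1 genotype would give. These percentiles describe these 2 libraries only.

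The list medians of the 3 secretory cell types were higher in the F4KO library. For Paneth cells, which secrete antimicrobial peptides at the crypt base, 18 measured genes had a median log2 fold change of 0.30 at percentile 100. Of them, 9 were higher and 1 was lower at an FDR of 0.001 or less in the authors' deposited table, 9 and 1 adjusted over the list alone, and 8 did not pass. The alpha-defensin Defa23 (chromosome 8, 21055047 to 21056016) had 208 reads in F4KO and 40 in WT, with an interval of the ratio from 3.72 to 7.55, Defa3 had 82 and 38 (1.46 to 3.29), and Defa26 had 145 and 81 (1.37 to 2.40). Defa32, which is outside the list, had 102 reads in F4KO and 12 in WT (4.70 to 17.1). Defa5 ran the other way with 35 and 62 reads, which did not pass with an FDR of 0.0412 in the authors' deposited table. The defensins are near-identical copies of one another, so the split of reads among them is uncertain. Outside the 10 defensin and defensin-like members, 8 measured Paneth genes had a median of 0.10 at percentile 93.7, inside the limits. Clps, which encodes colipase, had 749 reads in F4KO and 472 in WT, with an interval from 1.42 to 1.80. Lysozyme gene Lyz1 differed little, at 0.12 on the log2 scale with an FDR of 1.11e-05 in the authors' deposited table.

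Goblet cell genes, of the cells that secrete mucus, had a median of 0.27 over 19 measured members at percentile 100. Of these, 6 were higher and 1 was lower at an FDR of 0.001 or less in the authors' deposited table, 6 and 1 adjusted over the list alone, and 12 did not pass. Klk1, a kallikrein protease, had 509 reads in F4KO and 291 in WT, with an interval of the ratio from 1.52 to 2.04. The protease gene Tpsg1 was at 0.87 with an FDR of 1.66e-10 and Agr2, a protein disulfide isomerase needed for mucin folding, at 0.54 with an FDR of 1.74e-59 in the authors' deposited table. Bcas1, with 72 and 46 reads, did not pass (FDR 0.0752 in the authors' deposited table), and neither did the mucin gene Muc2, at -0.10 with an FDR of 0.642, named after its value was seen. Enteroendocrine cell genes, of the hormone-secreting cells, had a median of 0.27 over 25 measured members at percentile 100, with 6 higher, 7 adjusted over the list alone, and none lower at an FDR of 0.001 or less in the authors' deposited table. Those 6 were Ghrl, Gcg, Chgb, Cck, Gip and Chga, the first at 0.42 with an FDR of 1.53e-21 in the authors' deposited table. Secretin gene Sct had 83 reads in F4KO and 45 in WT (1.28 to 2.74), and the transcription factor gene Nkx2-2 had 112 and 68 (1.22 to 2.28). Their FDRs of 0.00599 and 0.00752 in the authors' deposited table did not pass, nor did that of 0.135 for the transcription factor gene Rfx6, which had 40 and 62 reads, or that of 0.206 for Pcsk1n. Tuft cell genes did not stand apart, with a median of 0.01 over 10 members at percentile 69.9 and none past the FDR, also adjusted over the list alone.

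**Figure D3:**
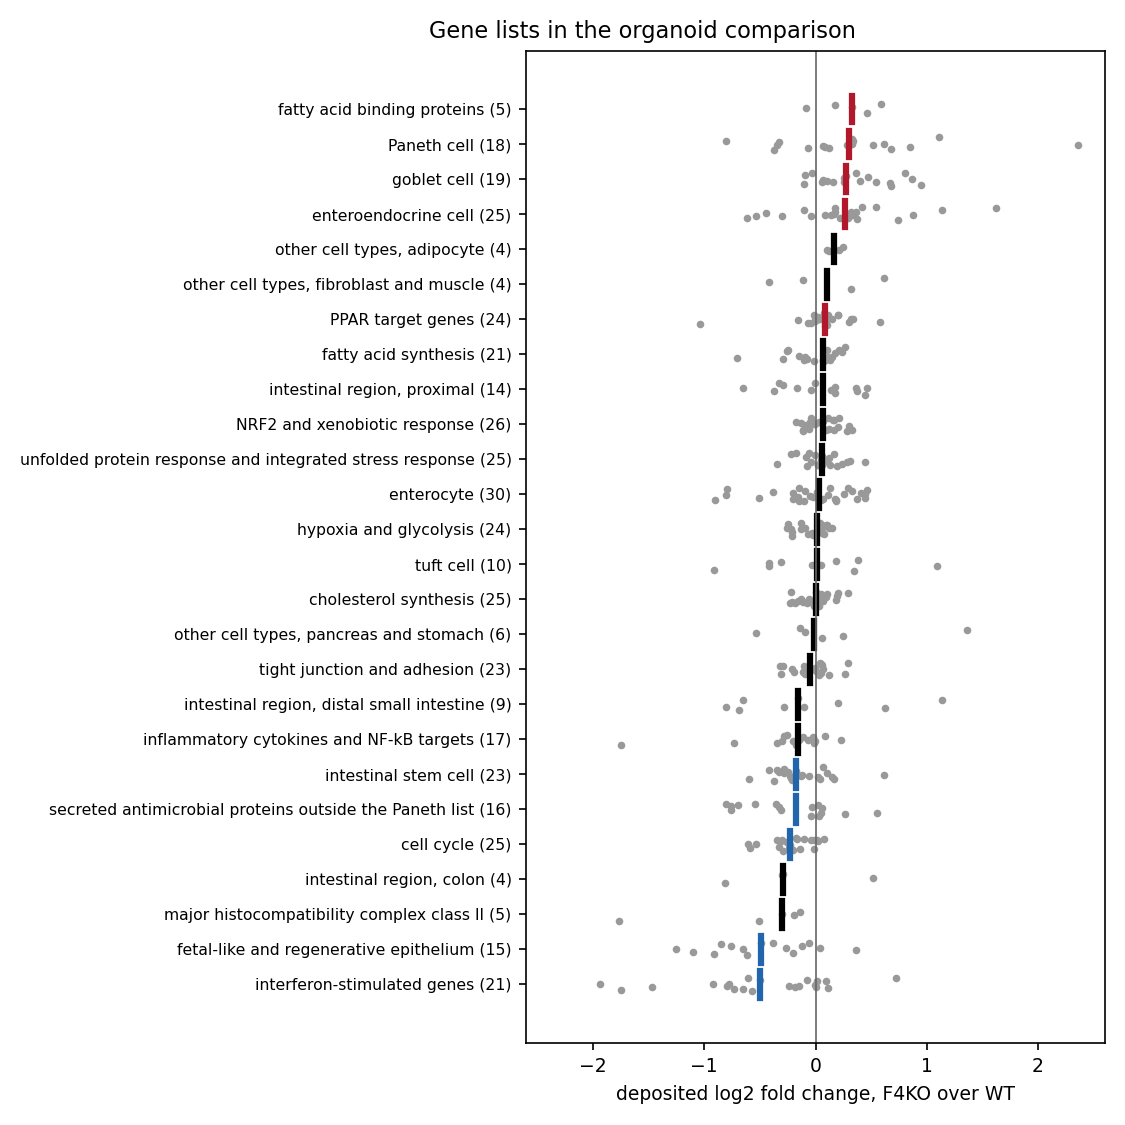
Each row is a gene list with its number of measured genes in brackets, each grey point is a gene's deposited log2 fold change of F4KO over WT, and the vertical bar is the list's median, red or blue where the list stood apart as higher or lower and black otherwise; the sex-linked list is not drawn. The medians run from -0.50 for the interferon list to 0.33 for the fatty acid binding proteins.

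The list medians of stem cell and proliferation genes were lower in the F4KO library. The intestinal stem cell list had a median of -0.18 over 23 measured members at percentile 0.36, with 1 higher and 8 lower at an FDR of 0.001 or less in the authors' deposited table and 1 and 8 adjusted over the list alone. Ascl2, a transcription factor of crypt stem cells (chromosome 7, 142966829 to 142969264), had 257 reads in F4KO and 392 in WT, with an interval of the ratio from 0.562 to 0.775. Lgr5, the R-spondin receptor that marks these cells, was at -0.34 with an FDR of 1.40e-12, and Igfbp4 was at -0.42 with an FDR of 1.90e-18 in the authors' deposited table. Tnfrsf19 had 131 and 171 reads and did not pass, and Smoc2 was the 1 member higher, at 0.15 in the authors' deposited table. The cell cycle list had a median of -0.23 over 25 members at percentile 0, with 22 below 0, and 11 were lower and 0 higher at an FDR of 0.001 or less in the authors' deposited table, 12 and 0 adjusted over the list alone. Bub1, a spindle checkpoint kinase, had 385 reads in F4KO and 582 in WT (0.585 to 0.760). Topoisomerase gene Top2a was at -0.60, the proliferation marker Mki67 at -0.53 and the mitotic kinase gene Cdk1 at -0.34, with FDRs of 3.62e-68, 6.93e-26 and 2.93e-17 in the authors' deposited table.

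The list of fetal-like and regenerative epithelium was lower by a larger margin. It had a median of -0.49 over 15 measured members at percentile 0, with 7 lower and 0 higher at an FDR of 0.001 or less in the authors' deposited table, 8 and 0 adjusted over the list alone. Ly6a, which encodes the surface protein Sca-1 (chromosome 15, 74994877 to 74998031), was past the size rule at -1.10 with an FDR of 1.33e-96 in the authors' deposited table. Sprr1a, a cornified envelope protein, had 185 reads in F4KO and 352 in WT, with an interval of the ratio from 0.441 to 0.635. The interleukin-1 receptor antagonist gene Il1rn had 375 and 680 reads (0.489 to 0.632), and the surface protein gene Ly6d had 545 and 929 (0.531 to 0.658).

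The medians of 2 lists of defence genes outside the Paneth list were lower in the F4KO library as well. Secreted antimicrobial genes had a median of -0.18 over 16 measured members at percentile 1.13, with 1 higher and 4 lower at an FDR of 0.001 or less in the authors' deposited table and 1 and 4 adjusted over the list alone. Reg3g, an antibacterial lectin, had 237 reads in F4KO and 404 in WT (0.502 to 0.696), and the dual oxidase gene Duox2 had 89 and 157 (0.436 to 0.746). Its maturation factor Duoxa2 had 41 and 67 reads and did not pass. The near-identical copies Sprr2a1 and Sprr2a2 went in opposite directions, at -0.76 and 0.55 on the log2 scale in the authors' deposited table, and their split is uncertain. Over the 15 genes with at least 100 reads this list was at -0.04 and percentile 28.5, no longer apart, whereas over all 22 with a fold change it was at -0.32 and percentile 0.08.

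Interferon-stimulated genes had a median of -0.50 over 21 measured members at percentile 0, with 16 below 0. Only 2 of these 21 were lower and 1 was higher at an FDR of 0.001 or less in the authors' deposited table, 2 and 1 adjusted over the list alone, and 18 did not pass. The lower ones were the interferon regulatory factor genes Irf7, with 205 reads in F4KO and 358 in WT (0.484 to 0.687), and Irf9, with 173 and 304 (0.473 to 0.694). Ifit1 had 41 and 79 reads and the immunoproteasome gene Psmb9 had 76 and 117, with FDRs of 0.00556 and 0.0254 in the authors' deposited table that did not pass. The higher one was the class I histocompatibility gene H2-K1, at 0.11 in the authors' deposited table. Over the 15 members with at least 100 reads the median was closer to 0, at -0.24 and percentile 0.32, still outside the limits. The summed reads of 9 immune cell markers with recovered read numbers were lower alongside, with 155 in F4KO and 238 in WT (0.533 to 0.807), most of them of Cd68 and Itgam. Rtp4, a chaperone induced by interferon, was among the largest differences with 10 and 48 reads (0.0947 to 0.420). Named after their values were seen, 4 further genes known as interferon-induced were past the size rule and lower. They were Ifi27 with 178 reads in F4KO and 528 in WT, Samd9l with 375 and 793, Dhx58 with 47 and 97, and Ddx60 with 18 and 55. Genes of inflammatory cytokines and NF-kB targets had a median of -0.16 over 17 members at percentile 3.42, inside the limits but past them at percentile 2.37 over the 13 with at least 100 reads, with 1 lower and 0 higher, and 1 and 0 adjusted over the list alone. The class II histocompatibility list had a median of -0.30 over 5 members at percentile 16.9, with 1 lower, 1 adjusted over the list alone, which was H2-Ab1 at -0.51 with an FDR of 5.34e-05 in the authors' deposited table.

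The lists of fatty acid binding proteins and PPAR targets had medians above 0 and stood apart as higher. The list of fatty acid binding proteins, the family of the targeted gene, had a median of 0.33 over 5 measured members at percentile 99.96, with 3 higher and 0 lower at an FDR of 0.001 or less in the authors' deposited table, 3 and 0 adjusted over the list alone. The retinol binding protein gene Rbp2 had 975 reads in F4KO and 715 in WT. Rbp2, Fabp2 and Fabp1, the last 2 being the intestinal and liver forms, were at 0.46, 0.33 and 0.17 with FDRs of 3.01e-09, 4.84e-13 and 4.32e-10 in the authors' deposited table. Fabp5 was at -0.09 with an FDR of 0.385 in the authors' deposited table. Fabp3 had 4 reads in WT and 0 in F4KO, and Fabp6 had 8 and 7. When every gene with a fold change was counted, the median of this list was 0 at percentile 48.3. Targets of PPAR, a family of nuclear receptors that respond to fatty acids, had a median of 0.09 over 24 members at percentile 98.0, just past the limit, with 3 higher and 1 lower, and 3 and 1 adjusted over the list alone. The acyl-CoA thioesterase genes Acot2 and Acot1, close copies whose split is uncertain, were at 0.58 and 0.32, Creb3l3 at 0.34 (FDR 0.0231, not passing) and the pantetheinase gene Vnn1 was past the size rule at -1.03, all in the authors' deposited table.

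Absorptive and remaining epithelial lists did not stand apart. Enterocyte genes had a median of 0.03 over 30 members at percentile 69.7, but went both ways, with 9 higher and 5 lower at an FDR of 0.001 or less in the authors' deposited table, 10 and 7 adjusted over the list alone. Fabp1 was among the higher ones. The lower ones included Mep1b, a brush border protease named after its value was seen, with 123 reads in F4KO and 232 in WT. Cholesterol synthesis genes had a median of 0.00 over 25 members at percentile 33.9 (2 higher and 5 lower, 3 and 5 adjusted over the list alone), and fatty acid synthesis genes had 0.07 over 21 at percentile 90.8 (3 and 1, then 5 and 1 adjusted over the list alone). The unfolded protein response list was at 0.05 over 25 and percentile 89.2 (2 and 2, then 4 and 3 adjusted over the list alone), and the NRF2 and xenobiotic list at 0.06 over 26 and percentile 89.8 (7 and 1, also adjusted over the list alone). Hypoxia and glycolysis genes were at 0.01 over 24 and percentile 41.7 (7 and 3, then 7 and 7 adjusted over the list alone), and tight junction and adhesion genes at -0.05 over 23 and percentile 11.3 (1 and 4, also adjusted over the list alone).

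Among the lists of regional identity and other cell types, none of those with a percentile lay outside the limits. Proximal intestinal genes had a median of 0.07 over 14 members at percentile 88.5 (5 higher and 1 lower, 6 and 1 adjusted over the list alone), distal genes -0.15 over 9 at percentile 22.2 (0 and 1, also adjusted over the list alone) but 0.05 over the 4 with at least 100 reads, and colon genes -0.30 over 4 at percentile 9.92 (1 and 1, also adjusted over the list alone). Of the colon list, Slc26a3, a chloride exchanger, had 612 reads in F4KO and 424 in WT, while the mucin gene Muc4 had 106 and 188. Fibroblast and muscle genes were at 0.10 over 4 members and percentile 76.5, adipocyte genes at 0.17 over 4 and percentile 92.4, and pancreas and stomach genes at -0.02 over 6 and percentile 61.7. None of these 3 lists had a member past the FDR, and 1, 0 and 1 were higher when adjusted over the list alone. Only 2 of 23 listed immune genes had at least 20 reads, Itgam with 56 in WT and 42 in F4KO and Cd68 with 165 and 104, too few for a percentile. Endothelial and blood genes also had 2 members counted as measured, of which Lyve1 had 144 and 118 reads. The other, Flt1, had no recovered read number and was counted only because no read pair fitted it. Its log2 fold change of -1 had a deposited Audic-Claverie p-value of 0.496, which needs few reads. The read rule that left these 2 lists without a percentile was settled after list results had been seen. With every gene with a fold change counted, immune genes had a median of -1 over 15 genes at percentile 2.34, outside the limits. With reads as the median of the fitting pairs they had -0.52 over 8 at percentile 0.05 and endothelial genes -0.64 over 4 at percentile 0.620. The 8 immune genes were Itgam, Cd68 and 6 without a recovered read number. Of these 6, Adgre1, Ms4a1 and Gzma were at -1, Cd79a at 0, Csf1r at 0.585 and Fcer1g at 1. Their deposited Audic-Claverie p-values ran from 0.504 to 0.994, so the immune percentile rests mostly on genes with few reads. Flt1 was again among the 4 endothelial genes, with Eng at -1 and Tek at 0, whose deposited Audic-Claverie p-values were 0.631 and 0.994. The endothelial median thus also rests mostly on genes with few reads, Lyve1 apart. No gene of mitochondrial DNA was analysed here.

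Single transcripts differed far more often than genes. In the authors' deposited table of 49739 transcripts, 39606 had a fold change, and 4697 were higher and 5002 lower in the F4KO library by the size rule. Of 7025 genes with 1 transcript that had a fold change, 34 transcripts (0.484%) were past the rule, against 9665 of 32581 transcripts (29.7%) of genes with several such transcripts. Among the 4586 genes with a transcript past the rule, 2113 (46.1%) had transcripts past it in both directions. For 94.6% of the transcripts past the rule the gene itself differed by less than 1.5-fold. How reads were divided among transcripts of one gene is not given in the sources used here, so no single transcript is named.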

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

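The tests of loss of the Y chromosome, of the Fam177a and zinc-finger copies, of the defensins, of immune cells and of culture or sex differences were chosen only after the result was seen, and that of animal sex was written after the Y-linked values had been seen and before the X-linked values it measures.

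The Epi comparison of the deposited tables, which the report leaves out and whose libraries the labels used here do not describe, held a far larger difference than the organoid comparison. There 1807 genes were higher and 160 lower in F4KO by the same size rule. Genes past the rule in opposite directions in the organoid and Epi comparisons numbered 12, and this difference was not tested. Of them 11 were lower in the organoid and higher in the Epi comparison, among them Ly6a, Myl9 and Pla2g5, but also H2-Q9, Fsbp and Zfp965, whose reads cannot be placed with certainty. Independent lists drawn from all 14962 genes with a fold change in both would share 4.29. That number is not matched on level, and genes with too few reads to pass lower it. The remaining 1, Fam177a2, was the reverse. With 1 library per genotype in the organoids, 5 lists that stood apart in both comparisons had medians of opposite sign in the Epi comparison, and none of these differences was tested. The Epi median log2 fold change was 1.47 for intestinal stem cell genes, 1.55 for cell cycle genes and 0.59 for secreted antimicrobial genes, all lower in the F4KO organoid library. It was -0.93 for fatty acid binding proteins and -0.41 for PPAR targets, both higher in the F4KO organoid library. Enteroendocrine genes, higher in the organoids, stood apart as lower in the Epi comparison at percentile 1.77, where their median of 0.17 was still above 0, and this was not tested either.

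The first pattern is the presence of Y-linked reads in the F4KO organoid library and their near absence in WT. Loss of the Y chromosome from the WT cells in culture would leave both libraries with 1 X chromosome, so X-linked genes that escape inactivation would not differ, but their median log2 fold change was -0.466, which argues against it. Animals of different sex predict a value below -0.2 for these genes, and the same -0.466 meets that prediction, so WT organoids from a female and F4KO organoids from a male animal are a candidate explanation. Sex alone does not account for the 30 reads of Uty in WT, against 1 each of Eif2s3y and Ddx3y, and their origin was not tested. The labels give no sex, and no gene outside X and Y can be freed from this difference with 1 library per genotype.

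The second pattern is the number of genes with near-identical copies among the largest differences. For Fam177a and Fam177a2, reads moved from one copy to the other predict opposite signs in each comparison. In the Epi comparison Fam177a2 was at -8.33 and Fam177a at 0.648. The median of that comparison was 0.35 and its upper quartile 0.81, so a gene without any exchange could be at 0.648, and this test decides little. A difference in how reads were assigned, or in the sequence of the copies between the animals, stays a candidate for both genes. For the zinc-finger region of chromosome 2, the reads summed over 11 genes gave a ratio of F4KO over WT of 0.674, with an interval from 0.619 to 0.733. A mere exchange among these 11 would leave the sum level, but 10 genes of the region, including Zfp965, had no recovered read number. An exchange with these cannot be told apart from a lower level of the region.

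The third pattern is the higher secretory lists together with the lower stem cell, cell cycle, fetal-like and interferon lists in the F4KO organoid library. An exchange of reads among the defensin genes would leave their sum level. Over all 23 with a fold change the reads summed to 22086 in WT and 27830 in F4KO, a ratio of 1.27 with an interval above 1.1, which argues against it as the whole rise. Reads were estimated from the p-value for 6 of them, and the interval takes these as exact. The 6 include Defa17 and Defa24, which held 85.4% of the WT sum, so the ratio mostly reflects these 2 genes, at 0.33 and 0.34 on the log2 scale. More immune cells in the WT culture as a source of the interferon difference would lower the immune genes in F4KO as well, and over 9 of them the summed reads were 238 in WT and 155 in F4KO, a ratio of 0.656 with an interval from 0.533 to 0.807. Most of these reads were of Cd68 and Itgam, whereas WT had 1 read each of Laptm5, Cd3e, Cd3d and Nkg7 and 6 of Lyz2. No read number was recovered for 6 further immune genes, but their deposited Audic-Claverie p-values, from 0.504 to 0.994, point to few reads. Ptprc and Tyrobp had no fold change. Genes so near the floor decide little, and Cd68, Itgam and Lyz2 were lower in F4KO, so immune cells cannot be told apart from a change within the epithelium. The loss of FABP4, the state of the cultures on day 6 and the sex of the animals all stay open and cannot be told apart, since each genotype had 1 library.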

How the results depend on the processing

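The alternatives at an FDR of 0.05, without X and Y, without the chromosome 2 region and with reads as the median of the fitting pairs were chosen after seeing the data, and the others were planned. The 17 higher and 38 lower genes depend mainly on the FDR filter. There were 1130 and 1275 with no FDR filter, 105 and 170 where the counting interval lay outside 1, and 59 and 116 at an FDR of 0.05, each a looser rule by construction. With at least 100 reads 12 were higher and 22 lower, and at 3-fold 13 and 20, both stricter rules. Without X and Y 12 and 35 were left, and without the chromosome 2 region 16 and 33. Setting the median or the trimmed mean of the fold changes to 0, shifts of -0.01 and -0.02, left 17 and 38 genes and moved no named gene across the rule. Transcripts numbered 8972 higher and 9621 lower with no FDR filter. When every gene with a fold change was counted, fatty acid binding proteins had a median of 0 (percentile 48.3, 9 genes) and no longer stood apart, immune genes had -1 (percentile 2.34, 15 genes), most of them with few reads, and antimicrobial genes had -0.32 (percentile 0.08, 22 genes). With at least 100 reads, antimicrobial genes had -0.0425 (percentile 28.5) and no longer stood apart, interferon genes had -0.24 (percentile 0.32, 15 genes) and still stood apart, and NF-kB targets had -0.15 and passed at percentile 2.37. With reads as the median of the fitting pairs, immune genes had -0.52 (percentile 0.05, 8 genes) and endothelial genes -0.64 (percentile 0.620, 4 genes). Most genes counted there in both lists had few reads, among them Flt1. Medians inside the limits changed sign for distal genes with at least 100 reads (0.05, 4 genes), for pancreas and stomach genes with every gene counted (0.06, 9 genes) or the trimmed mean set to 0 (0.00), and for cholesterol genes without X and Y (-0.01). For these lists the cause was not tested, beyond the change in the genes counted or the shift. The other lists with a value kept their side of the limits under these alternatives, the PPAR list at percentiles as low as 97.55. No paired analysis was possible because there is 1 library per genotype. Not run, for want of levels or counts per library, were other pseudocounts, count-based scaling factors, totals without the 50 most abundant genes, transcript sums per gene, counts scaled by library size, and a stricter filter for transcripts. Total depth is unknown.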

Other observations

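In the Epi comparison, proliferation and crypt genes were higher in F4KO and absorptive genes were lower. The authors' deposited table gave fold changes for 16336 genes there, and the median over 12330 genes with at least 20 reads was 0.35 on the log2 scale, so the values are best read against that shift. All 25 cell cycle genes were above 0, with a median of 1.55 and 22 past the size rule, among them the proliferation marker Mki67 at 1.71 in the authors' deposited table. Intestinal stem cell genes had a median of 1.47 over 21 members, tuft cell genes 1.32 over 16 and Paneth cell genes 1.03 over 21, each above percentile 99 of level-matched random lists. Olfm4, a stem cell marker, was at 1.54 with an FDR of 1.15e-182, and Dclk1, a tuft cell kinase, at 1.64 with an FDR of 3.76e-18 in the authors' deposited table. Enterocyte genes had a median of -0.51 over 30 members, 28 of them below 0 and 26 lower at an FDR of 0.001 or less, 26 adjusted over the list alone. The apolipoprotein gene Apoa4 was at -1.30, Rbp2 at -1.19, Fabp1 at -1.16 and Fabp2 at -1.14 in the authors' deposited table. Fabp4 was at 1.93 with an FDR of 0.213 in the authors' deposited table, which does not pass. Its 2 listed transcripts were at 5.39 and -3.46, with FDRs of 0.0587 and 0.689 that did not pass either. Fabp4 therefore does not check the genotype names of this comparison.

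Lipid genes of the Epi comparison went in opposite ways by pathway. Cholesterol synthesis genes had a median of 0.79 over 25 members, 24 of them above 0. Fatty acid synthesis genes had a median of 0.88 over 20 members, 15 above 0 and 5 below, with 14 higher and 3 lower at an FDR of 0.001 or less. Targets of PPAR had a median of -0.41 over 27 members, 24 below 0 and 19 lower at an FDR of 0.001 or less, 19 adjusted over the list alone. Pdk4, a kinase that restrains glucose oxidation, was at -2.92 and Angptl4, a lipase inhibitor, at -2.26 in the authors' deposited table. Class II histocompatibility genes had a median of -0.97 over 8 members, proximal intestinal genes -0.61 over 13, and NRF2 and xenobiotic genes -0.51 over 24. Fibroblast and muscle genes were higher, with a median of 2.22 over 14 members, including the smooth muscle actin gene Acta2 at 4.74 in the authors' deposited table, while endothelial and blood genes had -0.98 over 7 and adipocyte genes -0.79 over 4. In the endothelial and blood list the globin genes Hba-a1, Hba-a2 and Hbb-bs were at -2.57, -3.44 and -2.78 in the authors' deposited table. Of its endothelial genes, Plvap was at 1.84, Lyve1 at 0.42 and Pecam1 at -0.50, so the low median is not one of endothelial genes alone. Lists of other cell types thus differed as well as the epithelial lists in this comparison, in both directions. Genes in the text of this comparison were chosen after their values were seen.

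Across 11311 genes with at least 20 reads in both comparisons, the organoid and Epi fold changes had a Spearman rho of 0.00929 and a Pearson r of -0.0410 across genes, which are not independent replicates. Of the genes past the size rule, 4 were higher in both comparisons, against 1.91 for independent lists not matched on level, and 1, Igf2, was lower in both, against 0.361. The 4 were Defa23, Defa3, Bcl2l15 and 2210418O10Rik. Of 3753 transcripts past the rule in both comparisons, 49.8% had the same sign.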
